A study of Mus musculus with 8 samples.

How the data were processed

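RNA was measured in the whole inner ear of mice at postnatal day 14, in 4 samples of wild-type mice and 4 samples of heterozygous littermates carrying a frameshift that alters the function of thyroid hormone receptor α1 (TRα1), an isoform encoded by Thra. The sample labels give the tissue as inner ear, whereas the series title names the cochlea. RNA was extracted with TRIzol and a micro-scale silica column kit and made into libraries with a total RNA kit that carries unique molecular identifiers, per the labels' protocols. FastQC, STAR and HTSeq and the mouse genome build mm10 are named without versions, per the submitters' processing notes. The annotation, the counting options, the strand setting and whether the molecular identifiers were used to remove duplicate reads are not given in the sources used here. Each of the 8 deposited files holds counts per gene symbol, whole numbers that were not normalized, with 47517 symbols and no header line. Of these symbols 45236 are gene names of the GENCODE M21 annotation of GRCm38, the assembly that mm10 also names, from which the coordinates below were taken. In the files 15 symbols have the form of a date and a number, the mark of a spreadsheet conversion, and together they held at most 0.135% of the counts of a library.

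Total counts ranged from 18930841 to 23064578 per library, so a floor of 3 counts corresponded to between 0.130 and 0.158 CPM (counts scaled to the size of the library). Such floors and intervals cover counting error only. The lowest chi-square per degree of freedom between any 2 libraries was 14.7, so no 2 libraries agreed within sampling noise. The labels do not say whether a sample is 1 animal, a pool or 1 ear, nor which samples shared a litter, so p-values measure the spread between these samples, which may in part be technical. Replicate numbers were given in accession order and do not by themselves pair samples, but samples of the same number in the 2 genotypes also hold neighbouring title numbers. In each genotype the titles of replicates 1 and 4 hold 1 number and those of replicates 2 and 3 hold 2 numbers, and the labels do not say what the numbers stand for. This difference in title form was treated as a possible batch.

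The comparison of mutant with wild-type used edgeR 4.0.16 in R 4.3.3 on the deposited counts, with trimmed mean of M-values normalization, the default expression filter, robust quasi-likelihood dispersions and genotype as the only term. Of 33027 symbols with a count in any library, 21392 passed the filter, and a Benjamini-Hochberg adjusted p under 0.05 was required for a call. The standard error of a log2 fold change (mutant minus wild-type) is its size divided by the square root of the F statistic. CPM values were computed with the normalized library sizes. The 34 gene lists were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, and the adjusted p covers the 34 lists. For each list the test was repeated with a correlation estimated from the data, and the adjusted p was also computed over each list alone. A list score is the mean over its members of the log2 CPM (prior count 2) centred per gene. Scores and shares of counts were compared by two-sided exact permutation tests, whose smallest possible p with 4 against 4 libraries is 0.0286. The gene lists, the rule for named genes, the main test and the alternatives, apart from those said to be chosen later, were fixed before the data were examined.

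Named genes were Thra, 9 genes tied to hormone action or hearing (among them Thrb, Klf9, Hr, Dio3, Kcnj10, Slc26a5, Tecta and Otoa), up to 12 called genes per direction with a mean of at least 1 CPM, no overlap of the genotypes and an established symbol, up to 4 members of each called list and up to 2 of each other list. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were named as not past the threshold. These were drawn only from genes that met the same conditions on CPM, overlap and symbol. Members past the threshold within their own list, genes with all-or-none counts and the genes of the closing paragraphs were named after their values had been seen. The results of some genes that the rule names are not reported here.

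Alternatives were 3 other normalizations, no filter and a stricter one (CPM of at least 1 in at least 4 libraries), DESeq2 1.42.0, limma-voom, quasi-likelihood without robust estimation, a test against a fold of 1.2, each library left out in turn, title form, the Y-linked share of counts or 1 surrogate variable (sva 3.50.0) as covariate, neighbouring title numbers as a block, and haemoglobin, Y-linked genes and Xist left out. After the data had been seen, 3 more were added, in which genes with counts of exactly 0 in some libraries and at least 10 in every other library were left out, alone, with title form and with the block. Marrow scores were also compared within neighbouring title numbers by an exact sign-flip test chosen after the data had been seen. On simulated counts for 20758 of these genes the test of mutant against wild-type called 61 of 100 genes changed 2-fold and 91 of 100 changed 4-fold, with 0 in the wrong direction, and it also called 10 unchanged genes. The simulated list change was called, together with 2 other lists, both of which share genes with it. Genes were simulated independently, without the shared variation of real libraries, so this does not show how often unchanged lists are called.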

Results

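Gene expression in the whole inner ear was measured by total RNA sequencing at postnatal day 14, close to the onset of hearing in mice, a stage at which cochlear maturation depends on thyroid hormone. The comparison asked what differs in heterozygous mice whose Thra gene carries a frameshift altering TRα1, a nuclear receptor that represses or activates its target genes according to the hormone. Wild-type replicates 1 to 4 held 21790943, 19206844, 18930841 and 22028397 counts. Mutant replicates 1 to 4 held 23064578, 21431798, 20087114 and 19662433 counts, and the totals of the genotypes differed by less than the spread between libraries (exact permutation p = 0.571, n = 4 and 4). Mitochondrial genes took 10.2 ± 0.810% of counts in wild-type and 10.1 ± 1.10% in mutant libraries (SD, n = 4 each, exact permutation p = 0.943). Haemoglobin genes took between 0.781% and 4.87% of counts per library (2.59 ± 1.60% against 1.36 ± 0.529%, SD, n = 4 each, exact permutation p = 0.143). Xist, expressed from the inactive X chromosome, had 3622 to 10682 counts in every library. The Y-linked gene Eif2s3y had 545 and 520 counts in wild-type replicates 2 and 3 and 530 in mutant replicate 3, against at most 2 in each other library. The libraries with 520 or more Eif2s3y counts, which also had 3622, 6087 and 6228 Xist counts, all hold 2 numbers in the title. Both kinds of RNA together argue against a single animal as the source of each of these libraries. Mutant replicate 2, also with 2 numbers, had 0 Eif2s3y counts, so what the numbers stand for stays open. Y-linked RNA was thus not spread evenly over title form or genotype.

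Thra, the mutated gene (chr11:98740638-98769006, plus strand), was expressed in every library, at 114, 114, 102 and 98.4 CPM in wild-type replicates 1 to 4 and 137, 113, 126 and 132 CPM in mutant replicates 1 to 4. The means were 107 ± 8.28 and 127 ± 10.2 CPM (SD, n = 4 each), a log2 fold change of 0.24 (SE 0.089) that did not pass the threshold (edgeR adjusted p = 0.924). A frameshift cannot be seen in counts per gene, so these values do not check the genotype labels. Thra overlaps Nr1d1 on the opposite strand, and the strand setting of the counting is not known. Thrb, which encodes the other hormone receptor (chr14:17660261-18038090), stood at 30.8 ± 4.85 CPM in wild-type libraries with a log2 fold change of 0.14 (SE 0.16, n = 4 and 4) that did not pass.

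Of 21392 genes tested, 1 was higher and 8 were lower in mutant libraries at an adjusted p under 0.05 in edgeR. An unadjusted p under 0.05 was found for 1134 genes, 473 of them higher and 661 lower. That count was 692, 2512 and 651 without wild-type replicates 2, 3 and 4, and 1734 and 750 without mutant replicates 2 and 3. The largest fall in a called gene with counts in both genotypes was that of Bpifa1 (chr2:154142880-154149219, plus strand), a secreted antimicrobial protein of airway and middle ear mucosa. It fell from 299 ± 166 to 0.669 ± 0.438 CPM (SD, n = 4 each, log2 fold change -8.81, SE 0.64, edgeR adjusted p = 0.00701). Its lowest wild-type library held 3385 counts and its highest mutant library 26. Krt4, a keratin of moist stratified epithelium (chr15:101918535-101924735), fell by 5.84 on the log2 scale (SE 0.58, adjusted p = 0.0175). The basal-cell keratins Krt5 (chr15:101707070-101712898) and Krt14 (chr11:100203162-100207548), which pair to form filaments, fell by 5.31 (SE 0.53, adjusted p = 0.0175) and 3.61 (SE 0.38, adjusted p = 0.0223). Counts of Krt4 and of Krt5 in single mutant libraries lay between 0 and 2, so the size of both falls is known only roughly. Wisp2, a secreted matricellular protein also named Ccn5 (chr2:163820861-163833146), fell from 6.29 ± 1.58 to 0.783 ± 0.371 CPM (SD, n = 4 each, log2 fold change -2.99, SE 0.35, edgeR adjusted p = 0.0377). RP24-134N2.1, a symbol without an entry in the annotation used, fell from 3.62 ± 0.484 to 1.12 ± 0.226 CPM (SD, n = 4 each, log2 fold change -1.70, SE 0.21, edgeR adjusted p = 0.0489).

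**Figure D1:**
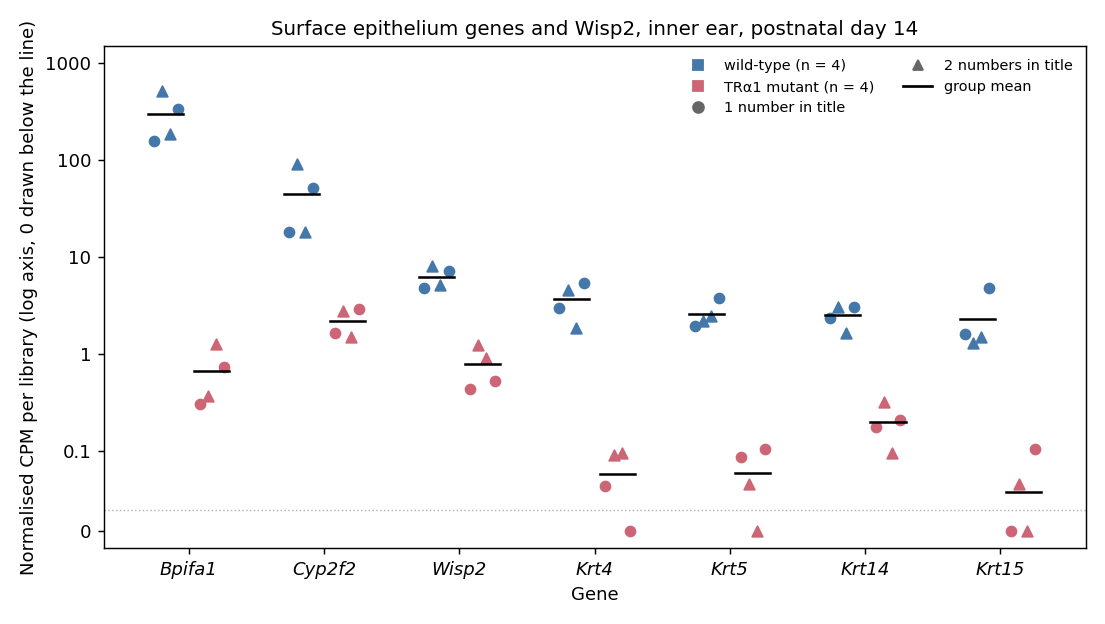
Normalised CPM (log axis, zeros drawn below the dotted line) of 7 genes in each wild-type (blue) and mutant (red) library, with circles for 1 number and triangles for 2 numbers in the title and black lines at the means of 4. Bpifa1 averaged 299 CPM in wild-type and 0.669 CPM in mutant libraries, and for Krt4, Krt5, Krt14 and Wisp2 the genotypes did not overlap either.

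The other 3 called genes had counts of exactly 0 in every library of 1 genotype. Gm26836, a long intergenic non-coding RNA of the minus strand that overlaps Ywhae (chr11:75745072-75761195), had 0 counts in the wild-type libraries and 3380 to 4586 in the mutant libraries. It was at least 1229-fold higher against a floor of 3 counts per library (edgeR adjusted p = 1.01e-04), while Ywhae itself had a log2 fold change of 0.11. Ankrd36 (chr11:5569684-5689337) had 73 to 93 counts in wild-type and 0 in mutant libraries, at least 29.7-fold lower (edgeR adjusted p = 0.00701). BC030870 (chr8:65085613-65129563) had 26 to 41 counts against 0, at least 11.9-fold lower (edgeR adjusted p = 0.0377). All 3 overlap other annotated genes, and counts of 0 beside counts of 10 or more occurred in 1071 tested genes, most of them without regard to genotype. With those genes left out, a choice made after seeing the data, 0 genes were higher and 13 lower in edgeR. Among these were the water channel Aqp3 (log2 fold change -5.56, adjusted p = 0.0264), the GABA receptor subunit Gabrp (-5.51, 0.0287) and the urothelial and mucosal membrane protein Upk1b (-3.80, 0.0442). The lung carbonyl reductase Cbr2 (-1.36, 0.0442) and the lymphoid chemokine Ccl21a (-3.23, 0.0406) were lower as well. With title form added, 6 genes were lower and these 5 lost their calls (adjusted p = 0.0503 to 0.137), at log2 fold changes of -5.55, -5.49, -3.78, -1.37 and -3.23 in the order given. With neighbouring title numbers as a block in place of title form, an assumed pairing, 163 genes were higher and 154 lower, among them Aqp3 (adjusted p = 0.0142), Gabrp (0.00953), Upk1b (0.00247), Cbr2 (0.0227) and Ccl21a (0.0221).

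Leaving out single libraries, which also reduces the replicates, changed these calls. Without wild-type replicate 4, mutant replicate 1 or mutant replicate 2, 4 genes were lower, and without wild-type replicate 1 there were 5. The number of higher genes was 2 without wild-type replicate 4 or mutant replicate 1, 3 without wild-type replicate 2 or mutant replicate 3, 4 without wild-type replicates 1 or 3 or mutant replicate 2, and 5 without mutant replicate 4. Bpifa1 kept its call with each library left out but lost it with neighbouring title numbers as a block, an assumed pairing (log2 fold change -8.71, adjusted p = 0.0643), as did Ankrd36 (-9.46, 0.0618) and BC030870 (-8.14, 0.0994). Krt4 and Krt5 lost theirs without wild-type replicate 4 (adjusted p = 0.0648 and 0.0735), mutant replicate 1 (0.0937 and 0.0798) and mutant replicate 2 (0.0516 and 0.0649). Krt14 lost its call without wild-type replicates 1, 2 or 4 or mutant replicates 1 or 4 (adjusted p = 0.0550 to 0.0937). Wisp2 lost it without each library but mutant replicate 2 (0.0734 to 0.142), BC030870 without each but mutant replicates 3 and 4 (0.0516 to 0.156) and RP24-134N2.1 without each of the 8 (0.0620 to 0.183). With each of the 8 libraries left out in turn, log2 fold changes lay between -6.14 and -5.49 for Krt4, -5.65 and -4.93 for Krt5, -3.93 and -3.39 for Krt14 and -3.31 and -2.79 for Wisp2. Where the other 2 lost their calls, log2 fold changes were -8.27 to -8.04 for BC030870 and -1.81 to -1.58 for RP24-134N2.1. With title form as covariate 1 gene was higher and 4 were lower, and 5 of the 9 called genes kept their call.

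On the higher side the 5 genes named did not pass the threshold in edgeR. They had the smallest p among genes whose genotypes did not overlap, so their separation was a condition of the choice. They were the alarmin Il33 (log2 fold change 0.84, SE 0.15, adjusted p = 0.261), Gprasp2, which sorts G protein-coupled receptors (0.35, SE 0.065, 0.278), and the collagen-binding proteoglycan Fmod (0.86, SE 0.16, 0.280). The neuronal calcium sensor Hpca (1.27, SE 0.26, 0.392) and the extracellular protein Myoc (1.16, SE 0.24, 0.433) completed them. DESeq2 called all 5, at adjusted p = 6.32e-04, 8.14e-05, 1.57e-04, 0.00256 and 0.00187 in that order. Genes with no overlap between genotypes numbered 575, or 2.69% of those tested, against 2.86% expected by chance.

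Of the genes chosen for their tie to hormone action, Hr, a corepressor and classical target of the hormone (chr14:70552212-70573548), stood at 21.9 ± 5.29 CPM in wild-type and 11.7 ± 3.18 CPM in mutant libraries without overlap (SD, n = 4 each, log2 fold change -0.91, SE 0.24, edgeR adjusted p = 0.867). With neighbouring title numbers as a block, an assumed pairing, Hr was called lower (-0.92, edgeR adjusted p = 0.0451). Klf9, another target (chr19:23141226-23168134), had a log2 fold change of -0.23 (SE 0.17, adjusted p = 0.980), and Dio3, which inactivates the hormone, had 45 counts over all libraries and was not tested. Adjusted over the list alone, 6 of the 22 tested thyroid hormone response genes passed. Hr, the circadian transcription factor Dbp (log2 fold change -0.31, SE 0.087) and the guanylate-binding protein Gbp3 (-0.65, SE 0.19) fell at an adjusted p = 0.0424 over the list. The calmodulin-binding protein Nrgn (-0.58, SE 0.18, adjusted p = 0.0450 over the list) and Flywch2 (-0.47, SE 0.15, 0.0492) fell too. Itih3, a heavy chain of the inter-alpha-trypsin inhibitor family that binds hyaluronan, rose by 1.42 (SE 0.39, adjusted p = 0.0424 over the list). Over all genes 0 of the list passed in edgeR without the block. With 10 members positive and 12 negative the list as a whole was not called (camera adjusted p = 0.329), whereas fry's test for change in either direction gave an adjusted p of 2.02e-04. The differences of Hr were -0.82 among libraries with 1 number in the title and -1.01 among those with 2.

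Genes of thyroid hormone receptors, transport and metabolism were called higher as a list (17 of 21 positive, camera adjusted p = 0.00590). With an estimated correlation the adjusted p was 0.307 and the call was lost. No member passed alone, adjusted over the list alone or over all genes. Crym, which binds the hormone in the cytosol (log2 fold change 0.66, SE 0.24), and Dio2, which activates it (1.38, SE 0.51, 53.4 ± 19.1 CPM in wild-type, SD, n = 4), had the smallest p besides Thra. Ttr, the carrier of thyroxine in plasma and cerebrospinal fluid, stood at 2020.82 CPM in mutant replicate 4 and at most 32.5 CPM in each other library. With Ttr left out, chosen after its values were seen, the list had an adjusted p of 0.0101, and 0.342 with an estimated correlation. The list score differed by 0.39 among libraries with 1 number in the title and 0.092 among those with 2. Over all libraries its exact permutation p was 0.0286, and 0.243 adjusted over the lists (n = 4 and 4).

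The airway and middle ear epithelium list fell as a group, with 17 of 18 tested members negative (camera adjusted p = 1.13e-40), and it was the only list called with an estimated correlation (adjusted p = 0.0179). Over all genes 4 members fell, the Bpifa1, Krt4, Krt5 and Krt14 given above, and adjusted over the list alone 8 did. The additional members were the basal-cell keratin Krt15 (log2 fold change -5.79, SE 0.82, adjusted p = 2.32e-04 over the list) and the club-cell enzyme Cyp2f2 (-4.33, SE 0.66, 6.98e-04). The mucin Muc16 (-2.63, SE 0.75, 0.0189) and the antimicrobial lectin Reg3g (-2.24, SE 0.73, 0.0317) fell likewise. The list score was lower by a difference of -2.07 among libraries with 1 number in the title and -2.11 among those with 2 (exact permutation p = 0.0286 over all, n = 4 and 4, the smallest that 4 against 4 libraries can give, adjusted over the lists 0.243). The 7 tested members of ciliated cells had a median log2 fold change of -0.13.

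Lists of sensory and supporting cells of the cochlea were not called. Hair cells (37 tested members, 28 negative, camera adjusted p = 0.329), outer hair cells (15 members, 0.549), supporting cells (24 members, 0.168) and the tectorial membrane and otic gel matrix (17 members, 0.124) did not pass. In each of them 0 members passed over all genes or adjusted over the list alone. With neighbouring title numbers as a block the matrix list was called higher (camera adjusted p = 1.42e-07). That list shares Col9a1, Col9a2, Col9a3 and Col11a1 with the cartilage list and Col5a2 with the fibroblast list, so the call is not specific to the tectorial membrane. Slc26a5, which encodes the outer hair cell motor prestin (chr5:21810655-21865604), had a log2 fold change of 0.39 (SE 0.31). The matrix genes Tecta (chr9:42329619-42399929) and Otoa (chr7:121081650-121163097) had log2 fold changes of -0.013 (SE 0.46) and 0.057 (SE 0.15), signs that turned when single libraries were left out. The hair cell genes with the smallest p were the calcium buffer Calb2 (-0.26, SE 0.15) and Tmie of the transduction complex (0.20, SE 0.13). Stard10 (-0.40, SE 0.15) and Lbh (-0.12, SE 0.081) came first among outer hair cell genes, and Bace2 (0.28, SE 0.11) and Fabp7 (0.56, SE 0.24) among supporting cell genes. In the matrix list the tectorial protein gene Ceacam16 (-0.55, SE 0.21) and Otos (0.32, SE 0.17) did. The otoconia and vestibular list (14 members, camera adjusted p = 0.395) and inherited deafness genes (93 members, 58 negative, 0.549) were not called either, with 0 members past either adjustment. Their leading genes included the anion exchanger gene Slc26a4 (-0.39, SE 0.15), Noxo1 (0.30, SE 0.15) and the epithelial transcription factor Grhl2 (-0.34, SE 0.12).

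Marginal cells of the stria vascularis, which secrete potassium into the endolymph, were called lower as a list (11 of 14 members negative, camera adjusted p = 0.0114). With an estimated correlation the adjusted p was 0.342 and the call was lost. The members with the smallest p were the transcription factor gene Esrrb (log2 fold change -0.31, SE 0.12), the sodium pump subunit Atp1b2 (-0.29, SE 0.13) and the potassium channel subunits Kcne1 (-0.34, SE 0.18) and Kcnq1 (-0.21, SE 0.15). Adjusted over the list alone 0 members passed. The score differed by -0.27 and -0.23 among libraries with 1 and 2 numbers in the title (exact permutation p = 0.0286 over all, n = 4 and 4, adjusted over the lists 0.243). The call was lost without wild-type replicate 3 (camera adjusted p = 0.203) or mutant replicate 2 (0.0537). Intermediate cells and melanocytes (17 members, camera adjusted p = 0.229), basal and spindle cells (10 members, 0.559) and potassium recycling genes (22 members, 18 negative, 0.124) were not called, with 0 members past adjusted over the list alone. The potassium recycling score differed by -0.14 and -0.15 among libraries with 1 and 2 numbers in the title (exact permutation p = 0.0286 over all, n = 4 and 4, adjusted over the lists 0.243), and the list was called lower with neighbouring title numbers as a block (camera adjusted p = 0.0391). Kcnj10, the strial potassium channel behind the endocochlear potential (chr1:172341210-172374085), had a log2 fold change of -0.11 (SE 0.16). Those of the melanosome gene Pmel, the endothelin receptor gene Ednrb and Sox8 were 0.29 (SE 0.12), 0.47 (SE 0.24) and 0.21 (SE 0.083). Spiral ligament fibrocytes were called higher (13 of 18 positive, camera adjusted p = 0.00514), and the adjusted p = 0.530 with an estimated correlation did not pass. The smallest p in this list was that of Dcn (0.33, SE 0.14), which is also in the fibroblast list. The transcription factor genes Tbx18 (0.39, SE 0.19), Pou3f4 (0.47, SE 0.23) and Dlx5 (0.54, SE 0.26) followed, and 0 members passed adjusted over the list alone. Dlx5 is also in the bone list, Lum in the fibroblast list and Ucma in the cartilage list. The fibrocyte score differed by 0.19 in both forms of title (exact permutation p = 0.200 over all, n = 4 and 4). The call was lost without wild-type replicate 2 (camera adjusted p = 0.217) or mutant replicate 4 (0.0633).

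Lists of blood-forming marrow and of dividing cells were called lower in mutant libraries. All 31 cell cycle genes had negative log2 fold changes (camera adjusted p = 3.71e-29, and adjusted p = 0.342 with an estimated correlation). The mitotic genes Cdc20 (-0.86, SE 0.25), Plk1 (-1.05, SE 0.34) and Top2a (-0.87, SE 0.29) and thymidylate synthase Tyms (-0.68, SE 0.22) came first, and 0 passed adjusted over the list alone. Of 20 B cell genes 19 were negative (camera adjusted p = 7.47e-19, and adjusted p = 0.307 with an estimated correlation). Adjusted over the list alone 6 fell, among them the precursor genes Dntt (-1.66, SE 0.38), Blnk (-0.97, SE 0.24), Vpreb3 (-1.11, SE 0.29) and Vpreb1 (-1.09, SE 0.29), each at an adjusted p = 0.0227 over the list. All 22 erythroid genes were negative (camera adjusted p = 5.24e-16, and adjusted p = 0.428 with an estimated correlation). Examples were the transcription factor gene Gata1 (-1.10, SE 0.43), Tspo2 (-1.10, SE 0.43), Rhag (-1.09, SE 0.50) and the iron importer Slc25a37 (-0.84, SE 0.37), with 0 past adjusted over the list alone. Score differences among libraries with 1 and 2 numbers in the title were -0.82 and -0.66 for cell cycle, -1.21 and -0.61 for B cells and -0.88 and -1.11 for erythroid cells. Exact permutation p values of these scores were 0.0857, 0.0571 and 0.114 (n = 4 and 4). Neutrophils (24 members, 20 negative, camera adjusted p = 0.497), macrophages (20 members, 0.329) and osteoclasts (17 members, 12 negative, 0.124) were not called. With neighbouring title numbers as a block neutrophils were called lower (camera adjusted p = 0.00519), but score differences within those pairs had both signs (-0.784, 0.104, 0.249 and -0.398). Of the neutrophil, macrophage and osteoclast members 1 fell adjusted over the list alone, the macrophage co-receptor gene Cd14 (-0.71, SE 0.16, adjusted p = 0.0406 over the list). Cd68 (-0.34, SE 0.19) and the osteoclast genes Calcr (-0.64, SE 0.26) and Itgb3 (-0.56, SE 0.26) did not pass. Nor did the neutrophil stefins Stfa1 (0.76, SE 0.35) and BC100530 (0.67, SE 0.33), whose counts are uncertain because they belong to a family of close copies.

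Connective tissue and skeletal lists were called higher. Of 24 fibroblast and collagen genes 23 were positive (camera adjusted p = 1.63e-13, and adjusted p = 0.351 with an estimated correlation). Adjusted over the list alone 1 rose, the matrix glycoprotein gene Fbln1 (log2 fold change 0.59, SE 0.12, 35.4 ± 2.87 to 53.1 ± 8.26 CPM, SD, n = 4 each, adjusted p = 0.0260 over the list). The tendon marker Tnmd (0.88, SE 0.34), fibronectin Fn1 (0.48, SE 0.19) and decorin Dcn (0.33, SE 0.14) followed. Osteoblasts and osteocytes (20 of 24 positive, camera adjusted p = 4.12e-05, and adjusted p = 0.543 with an estimated correlation) were led by bone sialoprotein Ibsp (0.81, SE 0.30, 800 ± 251 CPM in wild-type, SD, n = 4), Omd (0.49, SE 0.21) and Smpd3 (0.54, SE 0.25). Cartilage genes (14 of 21 positive, camera adjusted p = 0.00590, and adjusted p = 0.530 with an estimated correlation) included Scrg1 (0.45, SE 0.12), Comp (0.53, SE 0.15), Sox6 (-0.38, SE 0.21) and Lect1 (0.47, SE 0.31). No bone or cartilage gene passed adjusted over the list alone. With the block of neighbouring title numbers, an assumed pairing, and without all-or-none genes, edgeR called Ibsp (adjusted p = 0.0248), Col2a1 (0.00877) and Col9a1 (0.00631) higher. Score differences among libraries with 1 and 2 numbers in the title were 0.39 and 0.47 for fibroblasts, 0.11 and 0.48 for bone and 0.26 and 0.25 for cartilage. Over all libraries the exact permutation p values of these scores were 0.0571, 0.229 and 0.314 (n = 4 and 4). Bone lost its call without wild-type replicate 2 (camera adjusted p = 0.0754), and cartilage without wild-type replicate 2 (0.207) or mutant replicate 1 (0.0888).

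Myelin and vessel lists were called higher as well. Schwann cells and peripheral myelin (19 of 22 positive, camera adjusted p = 4.12e-05, and adjusted p = 0.530 with an estimated correlation) included the galactolipid enzyme gene Ugt8a (log2 fold change 0.42, SE 0.17), Mal (0.28, SE 0.13) and Mag (0.37, SE 0.18). Oligodendrocytes and central myelin (14 of 15 positive, camera adjusted p = 4.12e-05, and adjusted p = 0.530 with an estimated correlation) included Gpr37 (0.39, SE 0.12), the lineage factor gene Olig2 (0.72, SE 0.34) and Ermn (0.49, SE 0.27). Their score differences were 0.36 and 0.66 among libraries with 1 number in the title, against 0.11 and 0.032 among those with 2. The oligodendrocyte score was highest in mutant replicate 4, the library with the high Ttr, at 0.65, next to 0.59 in wild-type replicate 2 and at most 0.34 in each other library. Without mutant replicate 4 the list kept its call (camera adjusted p = 0.0117). Endothelial cells and pericytes were called higher (16 of 20 positive, camera adjusted p = 0.00614, and adjusted p = 0.662 with an estimated correlation), with score differences of 0.18 and 0.12. In that list Vwf (-0.51, SE 0.16) lay opposite to Emcn (0.62, SE 0.21), Kdr (0.49, SE 0.20) and the pericyte gene Cspg4 (0.38, SE 0.21). That call was lost without wild-type replicate 2 (camera adjusted p = 0.255), mutant replicate 1 (0.104) or mutant replicate 4 (0.213). No member of these 3 lists passed adjusted over the list alone. Ganglion and other neurons (31 members, 18 positive, camera adjusted p = 0.515) and central neurons and astrocytes (16 members, 0.329) were not called, with 0 members past adjusted over the list alone. The neurotrophin receptor gene Ntrk3 (0.27, SE 0.075), the growth cone gene Gap43 (0.58, SE 0.21), the glycine transporter gene Slc6a5 (1.51, SE 0.71) and the astrocyte water channel gene Aqp4 (0.39, SE 0.21) had the smallest p in them. Slc6a5 stood at 3.07 CPM in mutant replicate 4 and at most 0.630 CPM in each other library, and without that library the log2 fold change of Slc6a5 was 0.35 and the log2 fold change of Aqp4 0.18.

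**Figure D2:**
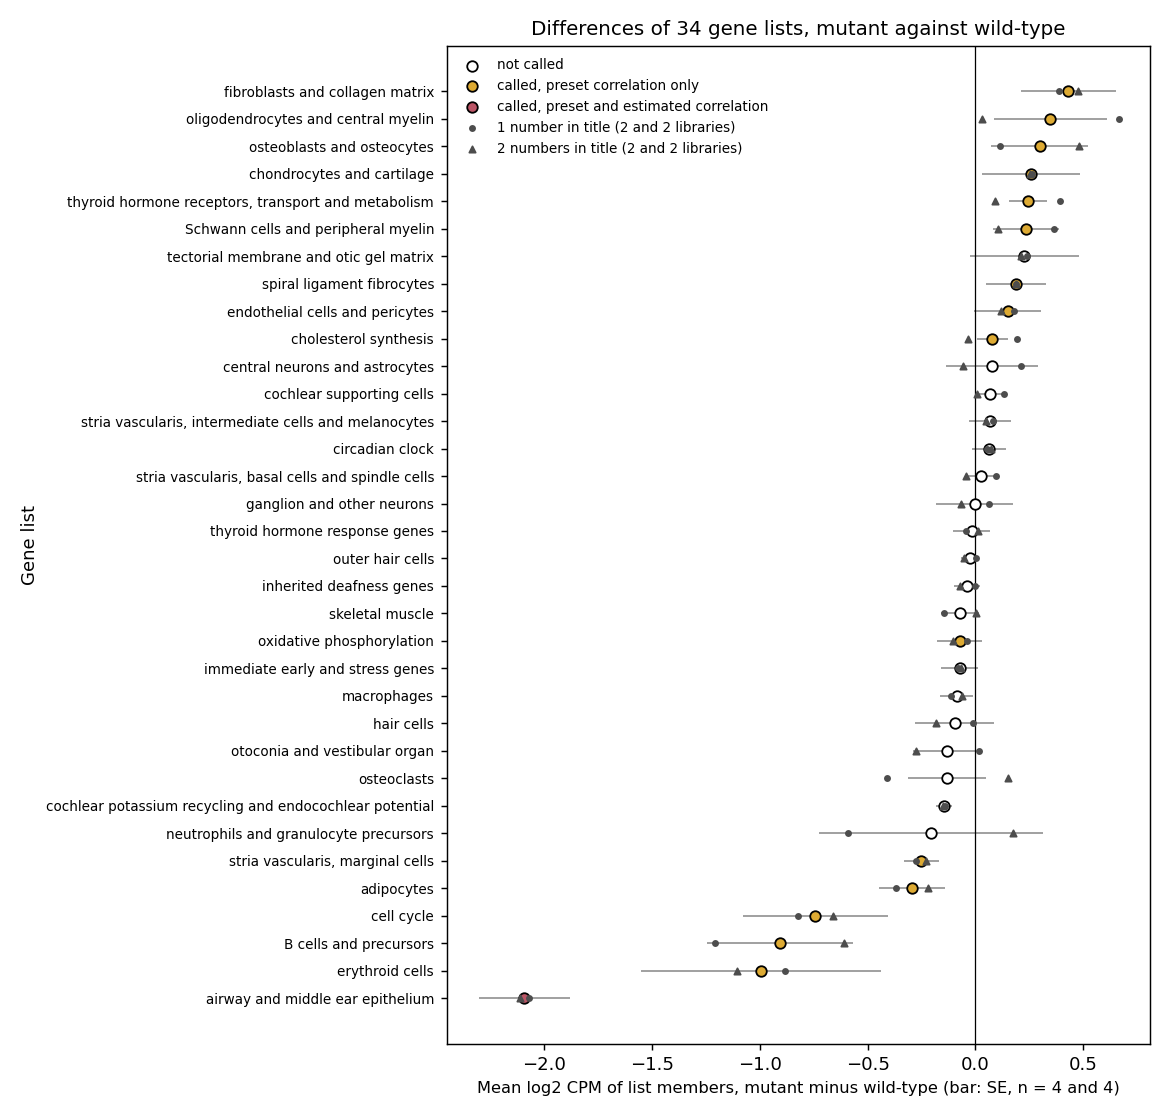
Difference in mean log2 CPM of list members, mutant minus wild-type, for 34 gene lists, with bars at 1 SE (n = 4 and 4), fill showing the camera call and small symbols the difference within each form of title. The airway and middle ear epithelium list lies farthest from 0 at -2.09, and the erythroid, B cell and cell cycle lists lie at -0.995, -0.91 and -0.74.

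Of the metabolic lists, adipocytes were called lower (7 of 9 negative, camera adjusted p = 0.0113, and adjusted p = 0.530 with an estimated correlation). The adipokine gene Adipoq (log2 fold change -1.33, SE 0.54), Plin4 of lipid droplets (-0.39, SE 0.12), the lipase gene Pnpla2 (-0.29, SE 0.094) and Lpl (-0.46, SE 0.19) had the smallest p. The call was lost without wild-type replicate 1 (camera adjusted p = 0.0511). Cholesterol synthesis was called higher (18 of 24 positive, camera adjusted p = 0.0437, and adjusted p = 0.662 with an estimated correlation). Examples were the genes of the pathway enzymes Hmgcs1 (0.23, SE 0.14) and Lss (0.18, SE 0.11). Its call was lost without wild-type replicates 2 or 4 (camera adjusted p = 0.0651 and 0.481) or mutant replicates 1 or 4 (0.237 and 0.306). Oxidative phosphorylation was called lower (30 of 33 negative, camera adjusted p = 0.0494, and adjusted p = 0.734 with an estimated correlation). Its first genes were Cox5b (-0.15, SE 0.11), Uqcrq (-0.13, SE 0.11), Ndufa1 (-0.16, SE 0.13) and Ndufa4 (-0.086, SE 0.075), all subunits of the respiratory chain. That call was lost without wild-type replicates 1 or 4 (camera adjusted p = 0.756 and 0.295) or mutant replicates 2 or 3 (0.930 and 0.470). Score differences among libraries with 1 and 2 numbers in the title were -0.37 and -0.22 for adipocytes, 0.19 and -0.034 for cholesterol synthesis and -0.040 and -0.11 for oxidative phosphorylation. Over all libraries the exact permutation p values of these scores were 0.114, 0.257 and 0.486 (n = 4 and 4). The circadian clock (19 members, 16 positive, camera adjusted p = 0.229), skeletal muscle (27 members, 0.549) and immediate early and stress genes (28 members, 0.375) were not called. Their leading genes besides Dbp were Tef (0.16, SE 0.12), the fast myosin light chain gene Mylpf (-0.60, SE 0.29), Tcap (-0.51, SE 0.33), Junb (-0.49, SE 0.17) and Btg2 (-0.57, SE 0.23). In these 6 lists 0 members passed adjusted over the list alone.

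In a principal component analysis without the genes of all-or-none counts, the first component held 31.4% of the variance and the second 28.3%. The first placed mutant replicates 1, 3 and 4 at 37.6, 26.2 and 21.2, above every wild-type library, and mutant replicate 2 at -24.7, below wild-type replicates 1, 3 and 4. The second followed the title form, with every library of 1 number in the title, the lowest at 3.17, above every library of 2 numbers.

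**Figure D3:**
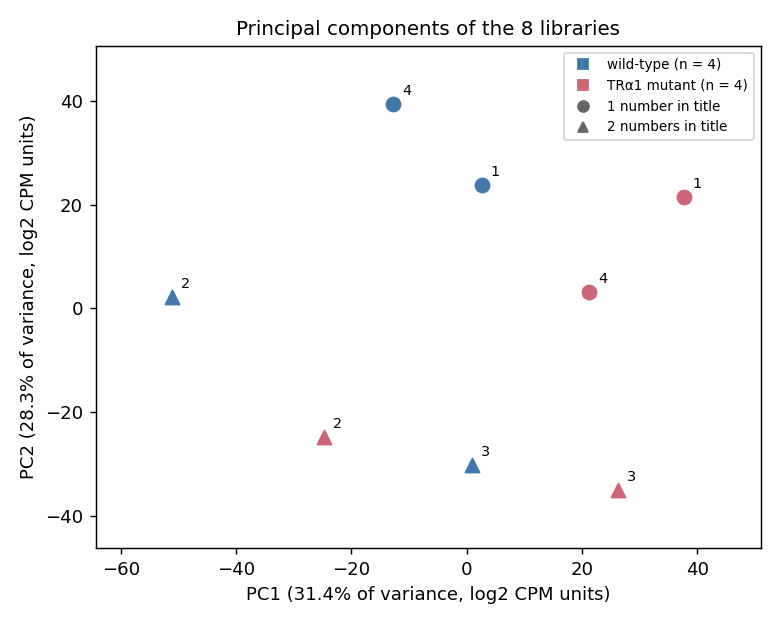
Positions of the 8 libraries on the first 2 principal components of log2 CPM, coloured by genotype (blue wild-type, red mutant), shaped by title form and numbered by replicate. The second component, with 28.3% of the variance, ranks the 4 libraries with 1 number in the title above the 4 with 2 numbers.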

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

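The tests of the epithelial genes, of the all-or-none counts and of the marrow lists were chosen after the results had been seen. The counts over other splits of the libraries were planned, except those without all-or-none genes.

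Of 329 groups of 4 values examined, 20 held a library whose gap to the nearest other exceeded 0.829 of the range, against 16.45 expected by chance, and Enpp2 and Slc4a5 had been named because they stood out. Ttr stood at 2020.82 CPM in mutant replicate 4 and between 5.96 and 32.5 CPM in the other mutant libraries. In the same library Aqp4 stood at 194 CPM (115 to 123 in the other mutant libraries), Slc6a5 at 3.07 CPM (0.388 to 0.598), Enpp2 at 659 CPM (171 to 195), Slc4a5 at 11.3 CPM (1.01 to 1.66) and Lss at 30.97 CPM (29.1 to 29.4). The score of strial marginal cells was -0.44 there, against -0.20 to -0.18 in the other mutant libraries. In mutant replicate 1 Vpreb1 stood at 4.61 CPM, against 2.76 to 2.91 CPM, and Aqp3 at 0.0878 CPM, against 0 in the other mutant libraries, which is a difference of few counts. In mutant replicate 3 Cspg4 stood at 26.8 CPM (19.7 to 20.9), Tcap at 1.07 CPM (1.75 to 1.84) and Zim1 at 13.8 CPM (5.08 to 6.28). In wild-type replicate 3 Cdc20 stood at 8.22 CPM (15.5 to 16.2 in the other wild-type libraries), Fbln1 at 39.6 CPM (33.6 to 34.3), Tef at 107 CPM (79.7 to 83.2) and the circadian clock score at 0.17 (-0.070 to -0.035). Peg10 stood at 4.83 CPM in wild-type replicate 2 (9.84 to 10.8). In wild-type replicate 4 Krt15 stood at 4.83 CPM (1.31 to 1.63), Fabp7 at 13.3 CPM (29.0 to 31.1) and Lss at 20.8 CPM (27.9 to 28.1).

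The fall of surface epithelium genes in mutant libraries may reflect the genotype or the tissue that came with each dissection. Lost counting in whole libraries is argued against, since 14 of the 16 counts of Bpifa1, Krt4, Krt5 and Krt14 in mutant libraries were above 0, and lower depth is too, since the mean total of mutant libraries was 1.03 times that of wild-type libraries. Middle ear lining carried into the wild-type dissections stays open: the 7 ciliated-cell members of the list had a median log2 fold change of -0.13 (range -0.46 to 0.018), but at a median of 3.53 CPM in mutant libraries, where other sources of these genes in the ear could hide a loss. No label records how the dissections were done, so the amount of adjoining mucosa and an effect of the mutation on this epithelium cannot be told apart. The list fell in both forms of title.

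Counts of exactly 0 in some libraries beside 10 or more in all others may come from the assignment of reads among overlapping genes. Of such genes in the annotation 88.7% overlap another gene, against 55.1% of other tested genes (Fisher's exact p = 6.86e-111, odds ratio 6.40), and among protein-coding genes the shares were 69.7% and 54.8% (Fisher's exact p = 4.39e-06). The mutation as the source of the set is argued against, since 11 of the 231 such genes at 0 in exactly 4 libraries followed the genotype, 5 at 0 in wild-type and 6 in mutant libraries. By chance 6.6 would follow it (one-sided exact binomial p = 0.0697), and the split of wild-type replicates 1 and 3 and mutant replicates 3 and 4 from the rest held 18. For Gm26836, Ankrd36 and BC030870 themselves the mutation and this behaviour of the counts cannot be told apart. Gm26836 and Ankrd36 lie on chromosome 11, as Thra does, and a variant linked to the mutated locus was not tested for them.

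The lower marrow lists could reflect less marrow in the mutant libraries or a change within it. A smaller share of marrow would lower erythroid, B cell and neutrophil scores alike. The genotype difference of the erythroid score minus the neutrophil score was -0.79 (exact permutation p = 0.143) and that of the B cell score minus the neutrophil score -0.70 (exact permutation p = 0.0571, n = 4 and 4), so 4 libraries per genotype leave the 2 readings open. With neighbouring title numbers as a block, an assumed pairing, the neutrophil list was itself called lower (camera adjusted p = 0.00519). The neutrophil score, however, differed within those pairs by -0.784, 0.104, 0.249 and -0.398, so it did not fall in every pair. Within the same pairs the B cell score minus the neutrophil score differed by -0.51, -0.51, -1.06 and -0.72 (exact sign-flip p = 0.125, the smallest that 4 pairs can give). The erythroid score minus the neutrophil score differed by 0.75, -1.45, -1.12 and -1.34 (exact sign-flip p = 0.250). Each genotype holds 2 libraries of each form of title, so title form alone cannot give a difference between genotypes. All 6 differences of erythroid, B cell and cell cycle scores within the forms were below 0. These come from the same libraries and are not independent.

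Chance could not be excluded for the counts of calls. Of the 35 splits of the 8 libraries into 4 and 4, the real one included, 3 called at least as many genes as the 9 of the real split, with 2092 as the highest of the others. The highest was the split by title form, at 2092 genes against 9, which points to a structure of the samples along the title form. The other, of wild-type replicates 1 and 3 and mutant replicates 3 and 4 from the rest, called 14. That split also held the 18 all-or-none genes given above. With title form as covariate the genotype fit called 1 gene higher and 4 lower. Without all-or-none genes 3 of the 35 splits reached the real count of 13, again with title form highest at 2292 and the genotype fit with that covariate at 0 higher and 6 lower. The next highest split, with 168 genes, set mutant replicate 2 with wild-type replicates 1, 2 and 4. These libraries also had the lowest fibroblast and collagen scores, at -0.49 to 0.12 against 0.38 to 0.72 in the others. Whether the tissue composition of the libraries underlies that split was not tested. For lists 8 of the 35 splits reached the real count of 16, with 20 as the highest other. The other splits called a median of 12 lists. With an estimated correlation 2 splits reached the real count of 1, with 1 as the highest other.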

How the results depend on the processing

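The alternatives without all-or-none genes were chosen after the data had been seen, the others before. The 9 called genes were all called under the other 3 normalizations and the stricter filter, where 1 gene was higher and 8 lower as in the reported comparison, and 7 were called without a filter. Leaving out haemoglobin, Y-linked genes and Xist gave 1 and 8, and the test against a 1.2-fold change 1 and 7. DESeq2 called 44 genes higher and 69 lower, 49 of these 113 with all-or-none counts, and limma-voom 5 higher and 11 lower. Without robust estimation 5 genes were lower, with the Y-linked share as covariate 5, with title form 4 and with 1 surrogate variable 4, each beside 1 higher gene. Leaving out all-or-none genes gave 0 higher and 13 lower genes and, with title form added, 0 and 6. With any 1 library left out, 2 to 5 genes were higher, 4 to 9 lower and 13 to 17 lists called. Of the 16 lists called at the preset correlation 1 was called with an estimated correlation and 1 by fry. The other settings that kept every library called 14 to 18. The causes of these changes were not tested.

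Neighbouring title numbers as a block gave 17 higher and 12 lower genes and 18 lists, and without all-or-none genes 163 higher and 154 lower and 17 lists. Since samples of the same replicate number hold neighbouring title numbers, it is also a block on replicate number. The block is an assumption, because the numbers are not stated to mark litters. Deviations from the group means correlated between neighbours at 0.13, 0.25, 0.19 and -0.038 over all tested genes, and at 0.35, 0.56, 0.49 and 0.10 without all-or-none genes, across genes, which are not independent replicates. In 5 of the 8 libraries the neighbour was the best match. Neighbours also share their title form. Wild-type and mutant pairs of the same form, neighbours included, averaged 0.078 over all tested genes and 0.25 without all-or-none genes. Neighbours of replicates 1 to 3 lay above these averages and those of replicate 4 below. Without all-or-none genes the common biological coefficient of variation was 0.185, against 0.153 with title form and 0.111 with the block. Title form alone may therefore not account for the likeness of neighbours, but these few pairs do not settle it. Every neighbouring pair exceeded 0.1 only without all-or-none genes, a set chosen after seeing the data, so pairing was not established over the genes reported. Of the 9 called genes 6 were called with the block. Without all-or-none genes it also called Bpifa1 (adjusted p = 1.84e-04), Hr (0.00773), Il33 (0.0325), Gprasp2 (0.0454), Fmod (0.0325), Hpca (0.00953) and Myoc (0.0136). Over all tested genes the block did not call these last 5 (0.0562 to 0.133). An unadjusted p under 0.05 was found for 2910 genes with the block. Cholesterol synthesis lost its call (camera adjusted p = 0.0889), and lists of the tectorial membrane and otic gel matrix (1.42e-07, higher), neutrophils (0.00519, lower) and potassium recycling (0.0391, lower) gained one. The matrix list shares collagen genes with the cartilage and fibroblast lists.

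For single genes 3183 values were recomputed, of which 3056 kept direction and side of the threshold, 53 lost a call, 66 gained one and 8 turned direction. The 8 were log2 fold changes of uncalled genes with 1 library left out. Thrb ranged from -0.019 (without mutant replicate 3) to 0.24, Kcnj10 from -0.25 to 0.0070 (without mutant replicate 2), Tecta from -0.57 to 0.26, positive at 0.038 and 0.11 without wild-type replicates 3 and 4 and 0.14 and 0.26 without mutant replicates 1 and 3, and Otoa from -0.041 and -0.0052 (without wild-type replicate 2 and mutant replicate 1) to 0.20. The common biological coefficient of variation was 0.292, and 0.185 without all-or-none genes. Low counts limit Krt4 and Krt5, which had at most 2 counts in any mutant library.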

Other observations

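The tests of imprinted genes, of title form, of choroid plexus and of long non-coding RNA without ribosomal loci were chosen after the results had been seen, whereas those of genes near Thra and of the total share of long non-coding RNA were chosen before.

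Imprinted genes that regulate fetal and postnatal growth, a list written after their values had been seen, lay higher in mutant libraries, with 18 of 19 tested members positive and a median log2 fold change of 0.36. H19, a growth-restraining non-coding RNA, stood at 60.4 ± 31.9 CPM in wild-type and 214 ± 133 CPM in mutant libraries (SD, n = 4 each, log2 fold change 1.83, SE 0.62). Within each genotype H19 was highest in replicate 3 and lowest in replicate 2, as was the fibroblast and collagen score. Whether both follow the amount of connective tissue was not tested. The Notch-pathway protein gene Dlk1 (1.25, SE 0.30), the zinc finger gene Plagl1 (0.74, SE 0.18) and Zim1 (1.29, SE 0.39) did not overlap between genotypes, whereas Peg10 (1.03, SE 0.37) and the growth factor gene Igf2 (0.64, SE 0.32) did. None passed over all genes without a block, where the smallest edgeR adjusted p was 0.701, and DESeq2 called Plagl1 (adjusted p = 0.0427). With neighbouring title numbers as a block, an assumed pairing, Zim1 passed in edgeR (1.24, adjusted p = 0.0451), and without all-or-none genes 9 members did, among them H19 (adjusted p = 0.00773), Zim1 (0.00953), Peg10 (0.0148), Plagl1 (0.0225) and Dlk1 (0.0431). A joint rise of the list may be one reading, since camera with an estimated correlation gave p = 0.0273, but the list score had an exact permutation p = 0.143 (n = 4 and 4), with differences of 0.56 and 0.45 among libraries with 1 and 2 numbers in the title. The same genes chosen for the pattern cannot test it independently.

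The form of the title went with more genes than the genotype did. With genotype in the fit and all-or-none genes left out, 1704 genes were higher and 571 lower in libraries with 2 numbers, of 20321 tested in edgeR. High Eif2s3y counts (520 to 545) stood only in libraries with 2 numbers, so an effect of sex was not separated from title form. The nuclear non-coding RNAs Neat1 (log2 fold change 1.04, SE 0.089, edgeR adjusted p = 0.00173), Meg3 (1.76, SE 0.19, 0.00288) and Miat (1.58, SE 0.17, 0.00291) were higher with 2 numbers. The ribosomal locus Rn18s-rs5 (-2.13, SE 0.33, 0.00962), the small nuclear RNA gene Rn7sk (-2.20, SE 0.31, 0.00582) and the axonal neurofilament gene Nefl (-0.54, SE 0.073, 0.00487) were lower. The lists of oxidative phosphorylation, ganglion neurons and endothelial cells were called lower with 2 numbers (camera adjusted p = 1.38e-11, 2.35e-08 and 3.44e-04), each with an adjusted p of 0.909 with an estimated correlation. More nuclear RNA in the libraries with 2 numbers may be one source, but as first tested the share of counts in long non-coding genes lay the other way, at 0.748 ± 0.0168% with 2 numbers and 0.870 ± 0.121% with 1 (SD, exact permutation p = 0.114, n = 4 and 4). The loci Gm42418 and AY036118, which take up ribosomal reads, held 29.9% of that share with 1 number. Without them, a choice made only after that result, the shares were 0.688 ± 0.0300% and 0.602 ± 0.00750% (exact permutation p = 0.0286, n = 4 and 4). The question therefore stays open.

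Choroid plexus, the epithelium that secretes cerebrospinal fluid and Ttr, is a candidate source of Ttr in mutant replicate 4. Of 16 other markers of that tissue 12 were highest in this library, against 2 expected by chance, at a median of 2.25 times the median of the other libraries. The most abundant of them, Enpp2, stood at 659 CPM there and at most 195 CPM elsewhere, and Slc4a5 at 11.3 and 1.66 CPM. Kcnj13 is also a marker of strial cells, and Igf2, Enpp2 and Trpm3 were abundant in every library.

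Sequence variants linked to the mutated locus could alter neighbouring genes. Within 10 Mb of Thra 25 of 344 tested genes had an unadjusted p under 0.05, or 7.27%, against 5.55% of genes elsewhere, a difference that did not pass Fisher's exact test (two-sided p = 0.190). Named genes in this window include Krt14, Krt15 and Top2a, for which linkage was not tested singly. Bpifa1, Krt4 and Krt5 lie on other chromosomes. Gm26836 and Ankrd36 lie on chromosome 11 with Thra but outside this window. All-or-none genes, these included, were left out of the test.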
